A study of Rattus norvegicus with 40 samples.

How the data were processed

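The series holds 40 reduced representation bisulfite libraries of T cells from Dahl SS rats, 1 from blood and 1 from kidney of each of 20 pools of 3 rats. The labels call the cells circulating and kidney T cells and give no isolation method, sort or gate. Libraries were read in 100 cycles of paired-end sequencing, with 13 or 14 libraries in a lane. The lane of each sample is not given, so that lane and group could not be told apart or tested. HS chow was fed for 3 weeks.

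The authors deposited 15 tables, each comparing 2 groups of 4 pools. No table holds a value per pool, a count or a read depth, so that the depth is unknown and no interval of a level or a difference could be computed. Intervals of shares of regions are binomial and treat regions as independent. Each table lists regions of at least 5 CpGs, segmented anew for that table, with a methylation level per group that the authors give as a fraction between 0 and 1, per the file headers, printed here in percent. The authors' difference is on the same scale. It departed from the difference of the 2 levels by over 0.2 percentage points in between 2.67% and 3.81% of the regions of a table. The deposited tables also give p-value columns: a Mann-Whitney p-value, its adjusted form, a further p-value, and a q-value. The adjusted form was checked to be the Benjamini-Hochberg adjustment of the Mann-Whitney p-value over the table (largest deviation 5e-16). Where under 1, the q-value was a median of 264401 to 416667 times the further p-value, by table. It is thus a column apart from the adjusted Mann-Whitney p behind the calls. Counts by it can differ in the test as well as in the limit. The authors' p-values reach 2.9e-14, whereas an exact rank test of 4 pools against 4 cannot go below 0.0286. They therefore treat CpGs of the same pool as independent, and speak of these pools rather than of rats in general. The aligner and the caller are not given in the sources used here. The build is rn5 per the submitters' processing notes, and the convention of the start coordinate is not stated. Columns of per-sample values left unused number 0.

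Levels were oriented as HS minus LS, CRL minus MCW, 10 minus 7 weeks and kidney minus blood. A region was called where the authors' adjusted p was under 0.05 and their difference was at least 10 percentage points. Since no per-pool values exist, no model was fitted, and calls rest on the authors' test. Gene names and the promoter, gene body or intergenic class are those of the tables. No rn5 annotation was at hand, and the RefSeq table of assembly GRCr8 served only to update names: of 12723 symbols in the tables, 11830 were current and 696 matched 1 synonym.

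Before the data were examined, the comparisons, the thresholds, 17 gene lists and the rule for named genes were fixed. The lists were T cell receptor and T cell identity, helper lineage transcription factors, cytokines and cytotoxic effectors, activation and exhaustion, trafficking and tissue residency, DNA methylation machinery, one-carbon metabolism, salt, renin-angiotensin and oxidant genes, innate and inflammasome signalling, aryl hydrocarbon and xenobiotic response, imprinted genes, homeobox developmental regulators, and markers of B cells, myeloid cells, natural killer cells, kidney epithelium, and endothelium and stroma. The rule named the genes of the 5 largest increases and decreases of each comparison (by position where most calls have no gene), genes with the most called regions, members of the lists with the largest called differences, genes called in the same direction in most tables of a family, and the DNA methyltransferases, Tet enzymes and main T cell genes. This last set was Dnmt1, Dnmt3a, Dnmt3b, Tet1, Tet2, Tet3, Ifng, Il17a, Foxp3, Cd4, Cd8a and Cd3e. Of its genes, only Dnmt1, Dnmt3a, Dnmt3b and Cd8a had a region in the tables.

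For each list, the genes with at least 1 called region were counted against 10000 random draws of genes of no list, matched on their number of tested regions (a permutation of genes, not of pools), two-sided, with Benjamini-Hochberg adjustment over the 17 lists of a comparison. The smallest p that the draws can give is 0.0002. Genes were not matched on their methylation level. As an added background, the draws were repeated over regions that could have passed, with at least 10% in 1 of the 2 groups. A region unmethylated in 1 group enters this background only by its change, so that no result on genomic context rests on it. Overlaps between tables were counted per direction over regions tested in both (at least 1 bp shared) against the number expected for independent lists, with Fisher's exact test, two-sided, adjusted over all overlaps of that rule. Overlaps were taken only between tables with no group in common. Genomic context was tested by Fisher's exact test against all tested regions.

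The methods were tested on simulated data: of 200 changed regions among 5000, 200 were called in the right direction with 0 false calls, 100 of 100 planted shared calls were found, and the planted gene list passed with 0 of the unchanged lists. The simulated CpGs were independent, with no difference between pools. The simulation therefore checks the computation only, and cannot show how many false calls arise where CpGs of a pool vary together. Values were computed with Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9, with the random seed 20240611. Other thresholds, autosomes only, merged regions, the authors' q-value column and other overlap rules were tried as alternatives.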

Results

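Reduced representation bisulfite sequencing measured DNA methylation in T cells from the blood and from the kidneys of Dahl salt-sensitive (SS) rats, an inbred strain whose blood pressure rises on a high salt diet. Rats came from 2 colonies, SS/MCW and SS/CRL, called MCW and CRL here. They ate a chow labelled LS or HS, read here as low and high salt. At 10 weeks of age there were 4 experimental groups (MCW and CRL rats on LS or HS chow), and a further group held MCW rats on LS chow at 7 weeks. Each group had 4 pools of 3 rats, and each of the 20 pools gave 1 blood and 1 kidney library, so that 40 libraries fell into 10 groups of 4. The values are the authors' methylation levels per region, averaged over the pools of a group. The deposited tables held no value per pool and no read depth, so that no spread or interval stands beside the levels. A region is called where the authors' adjusted p is under 0.05 and their difference is at least 10 percentage points. Positions are those of the rn5 build.

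Kidney against blood was the largest of the contrasts. Kidney T cell preparations were less methylated than blood T cells at most called regions in each of the 5 conditions. In MCW rats on LS chow at 10 weeks, 12995 of 42856 regions were called, of which 12006 were lower and 989 higher in kidney. The counts lower and higher were 13242 and 1814 for MCW HS, 10065 and 980 for CRL LS, 11808 and 1257 for CRL HS, and 12249 and 1277 for MCW LS at 7 weeks. The authors' q-value column is not the adjusted p behind these calls. With it under 0.05 and the same minimum difference, 2793, 2391, 2569, 2586 and 2436 regions passed. The order is MCW LS at 10 weeks, MCW HS, CRL LS, CRL HS and MCW LS at 7 weeks. The mean level over all tested regions was 35.9% in blood and 25.9% in kidney for MCW LS at 10 weeks, and 51.0% and 43.9% for MCW HS.

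More genes of T cell receptor signalling and T cell identity than expected carried a region called higher in kidney preparations in every condition. Of the genes of this list that had a tested region, 9 of 18 carried a region called higher in MCW LS at 10 weeks, where 0.932 were expected from genes matched on their number of regions. The other conditions gave 11 of 21 (MCW HS, 1.66 expected), 8 of 18 (CRL LS, 0.787), 10 of 19 (CRL HS, 1.12) and 11 of 18 (MCW LS at 7 weeks, 0.960). The adjusted p from 10000 random draws was 0.0034 in each of the 5, from a p of 0.0002 before adjustment, the smallest that the draws can give. Against matched genes with regions that could have passed (at least 10% in 1 group), the adjusted p stayed between 0.0017 and 0.0102. The promoter of Lat, the adaptor that links the T cell receptor to its signalling, was at 0.0403% in blood and 33.7% in kidney in MCW LS at 10 weeks, and at 0% and 27.6% in CRL LS. A gene body region of Lcp2, another adaptor of this pathway, was at 9.90% and 50.6% in MCW LS at 10 weeks. Cd247, the zeta chain of the receptor, went from 7.00% in blood to 63.6% in kidney in MCW HS. A promoter region of Cd8a, the co-receptor of cytotoxic T cells, was called higher in 4 of the 5 conditions, at 40.3% in blood and 64.2% in kidney in MCW LS at 10 weeks. In CRL HS its levels were 57.7% and 67.3%, a difference of 9.63 percentage points in the authors' deposited table, under the minimum of 10. The list held more lower than higher regions in every condition, with 11 higher and 18 lower in MCW LS at 10 weeks, 17 and 21 in MCW HS, 10 and 18 in CRL LS, 14 and 18 in CRL HS, and 15 and 19 in MCW LS at 7 weeks. Among the lower ones, Fyn was at 98.3% in blood and 16.7% in kidney, Skap1 at 77.5% and 15.7%, and Zap70 at 89.6% and 29.2% in MCW LS at 10 weeks. Lat, Lcp2, Skap1 and Zap70 were chosen after their values were seen.

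Genes that all leukocytes express, whether T cells or not, were counted in the same way with a list written after the data were seen. Of its genes with a tested region, 5 of 14 carried a region called higher in kidney in MCW LS at 10 weeks, 6 of 18 in MCW HS, 2 of 14 in CRL LS, 5 of 14 in CRL HS and 5 of 17 in MCW LS at 7 weeks. Genes with a lower region were more, at 7, 7, 8, 6 and 10 in the same order. Of these, CRL LS (3.54 expected, permutation p = 0.02) and MCW LS at 7 weeks (4.40 expected, permutation p = 0.01) passed against matched genes, and neither against those that could have passed (permutation p = 0.465 and 0.61). For the higher regions the permutation p against matched genes was 0.0006, 0.0002 (the smallest that the draws can give), 0.0882, 0.001 and 0.0002 in that order, and 0.0034, 0.0014, 0.282, 0.005 and 0.0058 against those that could have passed. The promoter of Nckap1l, a regulator of the actin skeleton in blood cells, was at 0.208% in blood and 36.3% in kidney in MCW LS at 10 weeks, that of Arhgap25 at 0% and 25.3%, that of Dok2, an adaptor of blood cells, at 19.4% and 62.4%, and a gene body region of Ikzf1, a transcription factor of lymphocytes, at 13.1% and 36.9%. Of the 30 genes of the list, 1 also stands in the T cell identity list.

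Most tested markers of kidney epithelium carried a region called lower in the kidney preparations in MCW LS at 10 weeks. The promoters of the organic anion transporters Slc22a8 and Slc22a6, of the proximal tubule, were at 92.5% and 86.2% in blood and at 9.00% and 14.0% in kidney in MCW LS at 10 weeks. Of the epithelial markers with a tested region, 24 of 33 carried a region called lower in this condition (25 called in either direction, and 25 adjusted over the list alone), where 15.3 were expected from matched genes (adjusted permutation p = 0.017). Against matched genes that could have passed, no condition gave an adjusted p under 0.05 for this list. Myeloid markers were lower at 9 of 12 genes and higher at 0 in MCW LS at 10 weeks, with Itgam, an integrin of myeloid cells, at 77.3% in blood and 13.0% in kidney. Of the endothelial and stromal markers, 11 of 20 were lower and 1 was higher, with Tie1, a receptor of endothelium, at 93.7% and 17.1%.

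Some of the largest decreases recurred in all 5 conditions. A gene body region of Runx1, a transcription factor of blood cell development, was at 93.3% in blood and 6.17% in kidney in MCW LS at 10 weeks, 92.1% and 23.6% in MCW HS, 92.7% and 3.81% in CRL LS, 94.3% and 9.25% in CRL HS, and 92.9% and 11.2% in MCW LS at 7 weeks. Jak3, a kinase of cytokine receptors, was at 95.8% and 6.82% in MCW LS at 10 weeks and at 95.4% and 1.86% in CRL LS. Map7, Prkce, Sh2d3c, Map3k14, Ascc1, Cdk17 and Epb41l5 were also called lower in all 5 conditions. Vps37d was too, though other regions of this gene were called higher in each. The largest decrease in MCW LS at 10 weeks was in Cd37, a tetraspanin of leukocytes, on chromosome 1 from 102296838 to 102296881, at 98.7% and 4.57%, with an adjusted p of 5.3e-07 in the authors' deposited table. Among increases, the promoter of Kcnn4, a calcium-activated potassium channel of T cells, was at 5.00% in blood and 63.0% in kidney in that condition, and at 3.33% and 72.1% in CRL LS. The promoter of Grap2, an adaptor of the T cell receptor pathway, was at 0% and 65.1% in MCW HS and at 0% and 69.9% in CRL HS. The promoter of Cybb, a subunit of the NADPH oxidase of phagocytes, was at 4.26% and 69.8% in CRL LS. Of the DNA methyltransferases, Dnmt3a carried called regions in every condition, with a gene body region at 78.5% in blood and 44.2% in kidney in MCW LS at 10 weeks, and a promoter region at 0.853% and 32.1% in MCW HS. Dnmt3b was called higher in MCW HS only, at 1.56% and 50.6%, and Dnmt1 in no condition.

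The 5 tables of kidney against blood shared no pools. Over regions that overlapped by at least 1 bp and were tested in all 5, 6143 were called in the same direction in all 5 (531 higher and 5612 lower), which was 66.1% of the 9289 that were called in MCW LS at 10 weeks. For the 10 pairs of tables, the shared calls were between 23.8 and 33.1 times the number expected for increases and between 2.51 and 3.35 times for decreases. Per pair and direction, at most 31 regions called in the first table were called in the opposite direction in the second. With regions that could have passed as background, the ratios were between 16.1 and 18.5 for increases and between 1.46 and 1.95 for decreases.

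**Figure D1:**
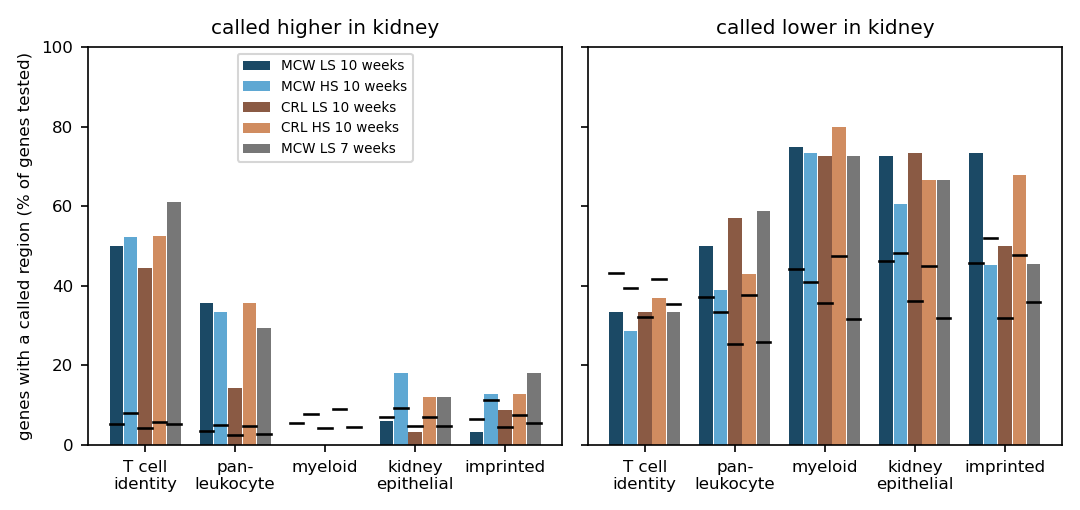
Percent of the tested genes of 5 lists that carried a region called higher (left) or lower (right) in kidney than in blood, in each of the 5 conditions; black lines mark the percent expected from genes matched on their number of tested regions. T cell identity genes stood above the expected share in the left panel in each condition, at 9 of 18 genes in MCW LS at 10 weeks.

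HS against LS chow was compared at 10 weeks within each tissue and colony, the question that the title of the series puts first. Blood T cells differed at few regions. In MCW blood, 67 regions were higher and 90 lower on HS chow among 33567. In CRL blood, 49 were higher and 95 lower among 35823. The authors' q-value column passed 7 regions in each of these tables. In MCW blood the promoter of Gnas, an imprinted locus that encodes the alpha subunit of a stimulatory G protein, rose from 22.8% to 44.3% over 21 CpGs (chromosome 3, 178440528 to 178440694, adjusted p = 5.75e-09 in the authors' deposited table). Sod3, the extracellular superoxide dismutase, rose from 60.8% to 81.2%. Shank3, a scaffold protein of synapses, fell from 56.1% to 32.9%, and Dclre1a, a DNA repair nuclease, from 75.5% to 51.4%. The shared promoter of the imprinted genes Nnat and Blcap fell from 49.5% to 33.7%, and that of Grb10 from 47.0% to 35.3%. Imprinted genes were the only list past the threshold in MCW blood: 5 of 28 carried a lower region (Nnat and Blcap by the same region), where 0.270 were expected (adjusted permutation p = 0.0034, and also 0.0034 against genes that could have passed). In CRL blood the promoter of Fbxl14, a subunit of a ubiquitin ligase, fell from 27.7% to 0.827%, with an adjusted p of 2.6e-08 in the authors' deposited table. Disc1 rose there from 74.6% to 94.2%. The Nnat and Blcap promoter fell in CRL blood too, from 52.6% to 36.4%. No list passed in CRL blood.

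Kidney preparations differed at many more regions, and mostly upward on HS chow at the limit of 10 percentage points. In MCW kidney 4424 regions were higher and 80 lower among 34115, and the mean level over all regions was 24.1% on LS and 28.5% on HS chow. In CRL kidney 1284 were higher and 167 lower among 39016, with mean levels of 17.5% and 18.3%. With no minimum difference the direction in CRL kidney turned, with 5972 higher and 7427 lower. The means of the CRL LS kidney group were equal (within 0.01 percentage points) in 40.6% to 51.6% of the regions that its tables share, against 98.8% to 99.1% for MCW HS kidney and 63.2% to 75.1% for MCW LS kidney at 10 weeks. The authors' q-value column under 0.05 passed 372 and 57 regions in these tables. The difference between the tissues in the salt effect was not itself tested, since the tables hold no value per pool.

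Imprinted genes stood out in the MCW kidney comparison, where 19 of 31 carried a region called higher and 0 a region called lower (8.02 expected, adjusted permutation p = 0.0034; 0.0068 against genes that could have passed). The draws matched genes on their number of regions, not on their level. Imprinted genes also had more called genes than any other list in each comparison within blood. These were 5 of 28 and 3 of 27 for salt (MCW and CRL), 5 of 33 and 4 of 31 for colony (LS and HS chow), and 4 of 31 for age. A high count for this list was therefore not particular to this comparison. Of the 18 Gnas regions 15 were called, each higher, with a gene body region going from 30.5% to 66.7%. Grb10, an adaptor that restrains insulin receptor signalling, had 8 of 9 regions called higher. The promoter of Plagl1, a growth regulator, rose from 22.0% to 54.1%, that of Zrsr1 from 15.9% to 45.9%, that of Snrpn from 21.0% to 38.3% and that of Peg3 from 27.1% to 43.5%. Snrpn and Peg3 were named after their values were seen. The largest single increase was at the promoter of Ndufa10, a subunit of respiratory complex I, from 8.98% to 61.8%, with an adjusted p of 4.2e-11 in the authors' deposited table. In blood of the same rats that promoter fell, from 62.8% to 39.9%.

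Regions called higher on HS chow in MCW kidney included markers of other cell types as well as T cell genes. Of the kidney epithelial markers 14 of 30 carried a region called higher and 0 a lower one, with Ggt1, an enzyme of glutathione breakdown, at 16.3% on LS and 55.0% on HS chow, the Slc22a6 promoter at 14.0% and 43.4%, Aqp1, the water channel of the proximal tubule, at 18.7% and 47.2%, and Lrp2, its uptake receptor, at 45.8% and 73.8%. Endothelial and stromal markers were higher at 8 of 21 genes, myeloid markers at 3 of 10, and T cell identity genes at 7 of 17, among them Cd8a (promoter, 37.7% and 69.6%), Lef1 (52.0% and 78.1%) and Zap70 (29.2% and 45.3%). Of salt, renin-angiotensin and oxidant genes 7 of 28 were higher, with Nedd4l, a ubiquitin ligase that acts on the sodium channel, at 7.37% and 37.7%. None of these lists passed the threshold against matched genes, which does not show that their counts were those expected. Homeobox genes were called less often than matched genes, at 9 of 63 where 20.3 were expected (adjusted permutation p = 0.0085), but not against genes that could have passed. Lef1 and Zap70 were chosen after their values were seen. The Cd8a promoter level of MCW LS kidney here is lower than the one given for kidney against blood. Regions are segmented anew per table, and the means of that group were equal in 63.2% of the regions that these 2 tables share. Whether the 2 levels describe the same stretch was not tested.

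In CRL kidney a region of Slc38a4, an amino acid transporter, rose by 41.8 percentage points to 66.8%, with an adjusted p of 8.79e-09 in the authors' deposited table. Tbxa2r, the thromboxane receptor, rose from 16.7% to 56.4% and Nfkb1, a subunit of NF-kappa B, from 14.1% to 45.6%. Imprinted genes carried a higher region at 9 of 27 genes (2.17 expected, adjusted permutation p = 0.0102), among them Plagl1 (19.2% and 42.2%), Zrsr1 (7.07% and 29.5%) and Igf2r (10.2% and 29.4%). This list did not pass against genes that could have passed. Decreases included the epithelial secretory gene Wfdc2 (63.0% and 28.8%), the tight junction gene Cldn10 (49.5% and 17.7%), Hoxc10 (47.5% and 21.4%) and Pax2 (46.7% and 28.1%), both developmental regulators. Of the epithelial markers 5 of 27 were higher and 1 was lower, and of T cell identity genes 3 of 18 were higher.

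Regions were also sorted by the kidney against blood tables of the other colony, which share no rats with the salt table in question. Of 4700 regions that the CRL tables called lower in kidney than in blood, 99.0% rose on HS chow in MCW kidney, with a median change of 11.3 percentage points. Of 377 regions that they called higher in kidney, 81.2% rose, with a median change of 6.52. The 753 regions at 60 to 90% in blood with under 5 percentage points between tissues had a median change of 2.01, and 809 regions under 5% in both tissues one of 0.353. In CRL kidney, sorted by the MCW tables, 81.4% of 2527 regions lower in kidney rose (median 6.32) and 56.3% of 206 regions higher in kidney (median 3.00). There the 817 regions at 60 to 90% had a median change of -1.66, with 33.8% rising, and the 842 regions under 5% one of 0.

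Imprinted loci carry 1 methylated parental copy as a rule, and regions of these genes at 30 to 60% in blood had a median over genes between 39.2% and 42.3% in the blood of the 5 conditions. In kidney this median was 22.5% in MCW LS at 10 weeks against 41.6% in blood (17 genes), and 27.3% in CRL LS against 40.5%. It was 40.4% in MCW HS against 39.5% in blood, 37.2% in CRL HS against 42.3% and 35.6% in MCW LS at 7 weeks against 39.2%. With genes that share regions, such as Nnat and Blcap, counted as 1 locus, kidney was lower at 14 of 15 loci in MCW LS at 10 weeks (exact sign test p = 0.000977), 14 of 15 in CRL LS (exact sign test p = 0.000977), 7 of 16 in MCW HS (exact sign test p = 0.804), 13 of 16 in CRL HS (exact sign test p = 0.0213) and 9 of 14 in MCW LS at 7 weeks (exact sign test p = 0.424). These genes were tested after the list result was seen. The sign tests take loci as independent, though all loci of a condition come from the same libraries. They speak of loci, not of pools or rats.

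**Figure D2:**
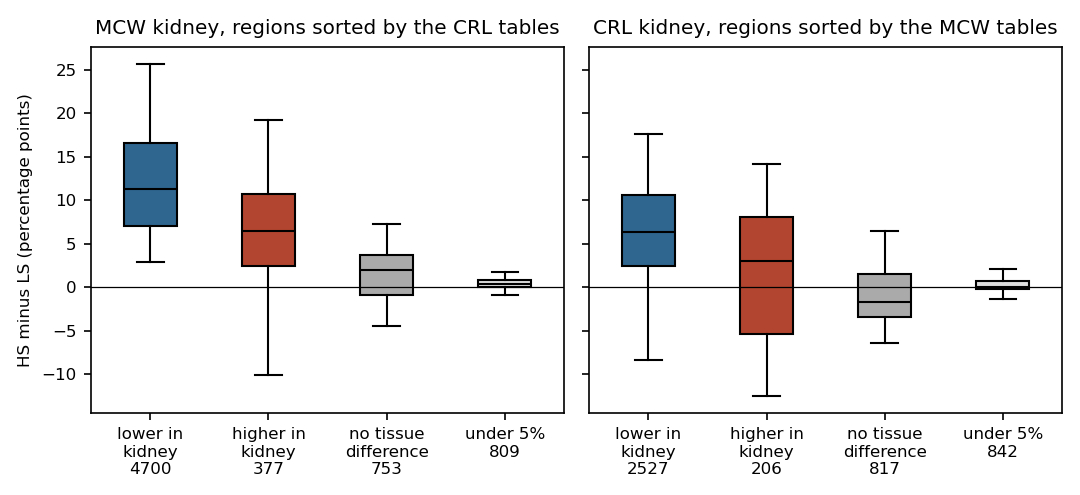
Change in methylation (percentage points, HS minus LS chow) of kidney regions in MCW (left) and CRL (right) rats, sorted by the kidney against blood tables of the other colony; boxes are quartiles with the median, whiskers the 5th and 95th percentiles, and numbers below are regions. In MCW kidney the median change was 11.3 for regions lower in kidney and 6.52 for regions higher in kidney.

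The MCW and CRL salt tables came from separate rats. In kidney, 908 of the regions tested in both were called higher in both, where 206.3 were expected, and 907 against 395.7 with regions that could have passed. Among decreases 13 were shared, where 0.364 were expected (Fisher's exact test, adjusted p = 3.36e-17), and 25 of the MCW increases were CRL decreases. In blood, 4 decreases were shared (0.246 expected, Fisher's exact test, adjusted p = 0.00012) and 1 increase (0.0783 expected, adjusted p = 0.0799), while 4 MCW increases were CRL decreases and 3 MCW decreases were CRL increases. Between blood and kidney of MCW rats, 26 increases were shared (6.92 expected, Fisher's exact test, adjusted p = 1.63e-10), whereas 26 of the 57 blood decreases tested in both tissues were kidney increases, and 0 decreases were shared. In CRL rats 2 increases (1.18 expected) and 2 decreases (0.254 expected, Fisher's exact test, adjusted p = 0.029) were shared, the decreases no longer past the threshold with regions that could have passed (adjusted p = 0.074) or by gene (adjusted p = 0.0616), and 12 blood decreases were kidney increases. Blood and kidney libraries came from the same pools of rats, which these expected numbers and p ignore. Disc1 and Gnas carried a region called higher on HS chow in all 4 salt tables, and Gnas carried a lower one in 2 of them.

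**Figure D3:**
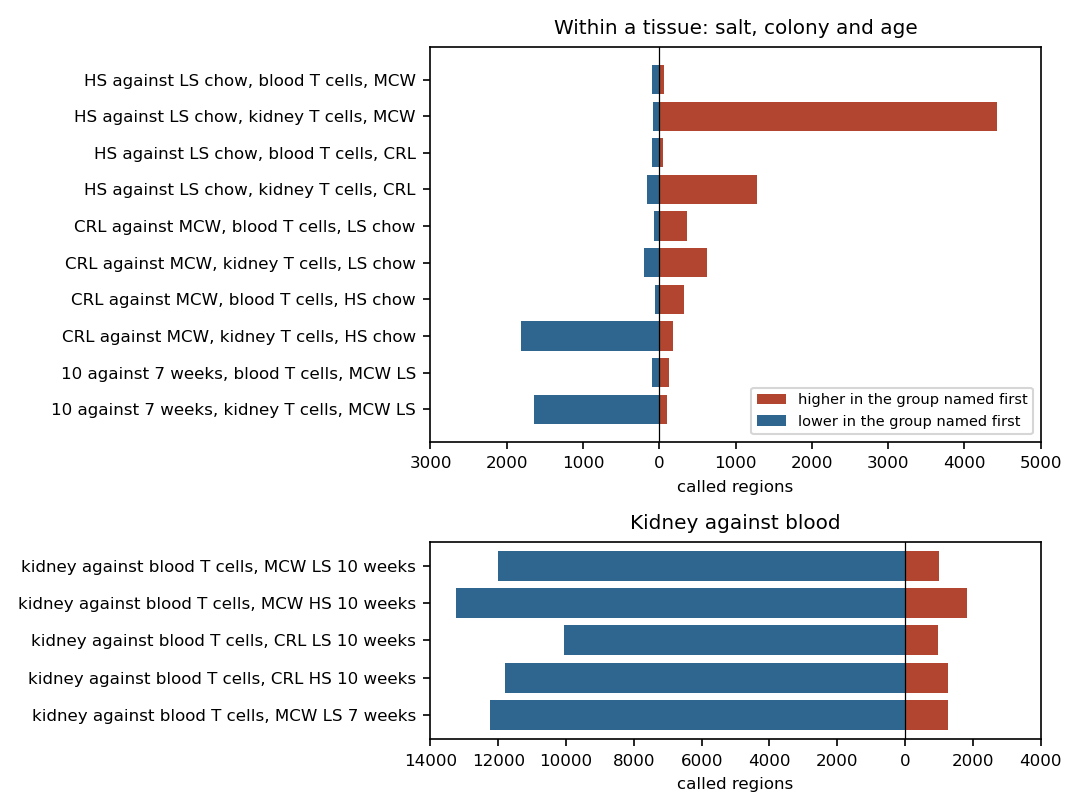
Number of called regions in each of the 15 comparisons, higher (red, to the right) and lower (blue, to the left) in the group named first; the panels have separate axes. Kidney of MCW rats on HS against LS chow had 4424 regions higher and 80 lower.

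**Figure D4:**
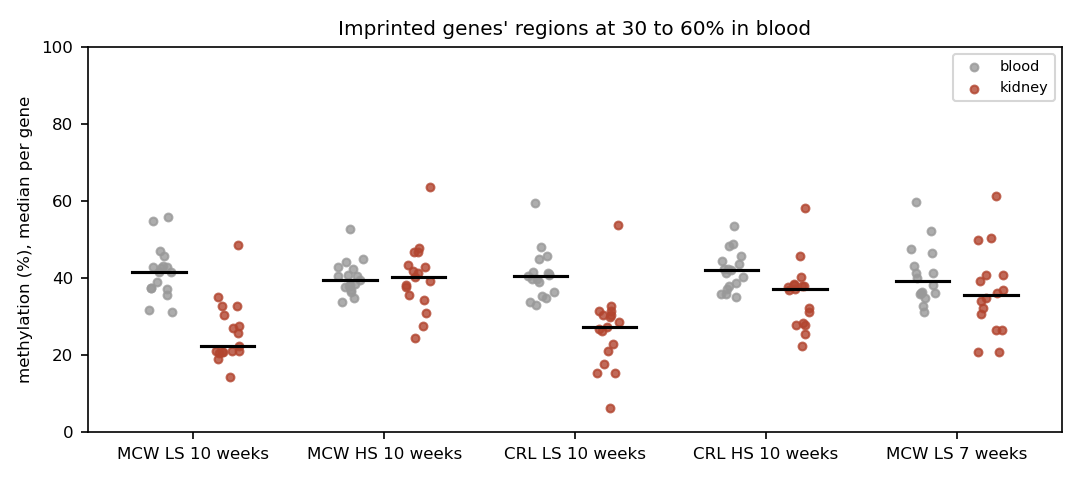
Methylation (%) of imprinted genes in blood (grey) and kidney (red) in each condition; a point is the median over a gene's regions at 30 to 60% in blood, and lines are medians over genes. The kidney median was 22.5% in MCW LS at 10 weeks and 40.4% in MCW HS.

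CRL against MCW rats compared the colonies, which the labels give as rat types. A colony and its maintenance diet cannot be told apart in this comparison. Blood of CRL rats was more methylated at 369 regions and less at 64 on LS chow, and at 318 and 56 on HS chow, and the authors' q-value column under 0.05 passed 74 and 64 regions. A gene body region of Shank3 was at 10.4% in MCW and 47.1% in CRL blood on LS chow (adjusted p = 1.01e-11 in the authors' deposited table) and at 18.5% and 44.2% on HS chow. Pik3cd, a lipid kinase subunit of lymphocytes, was at 22.0% and 49.9% on LS chow, Sod3 at 68.1% and 92.5%, and Ptprs, a receptor phosphatase, at 60.1% and 91.0% on HS chow. For the 5.8S ribosomal RNA gene, listed as Rn5-8s, 31 of 132 regions were called on LS chow in blood, 29 of 117 on HS chow, 13 of 160 in kidney on LS chow and 24 of 173 on HS chow, each of them higher. Those regions are repeated copies, and copies with equal values are counted more than once. Among imprinted genes, Igf2r was at 15.0% and 31.6% in blood on LS chow and Zrsr1 at 34.5% and 52.9%, while a promoter region of Grb10 was lower, at 64.9% and 45.5%. Ccr7, the receptor that guides T cells to lymph nodes, was at 23.7% and 38.7% on LS chow and at 23.6% and 37.5% on HS chow. In blood, 143 increases were shared between the LS and HS tables, which had no rats in common (7.32 expected, Fisher's exact test, adjusted p = 5.19e-159).

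In kidney the colony difference went mostly up on LS chow and mostly down on HS chow, though the difference between the chows was not itself tested and, with no minimum difference, 6007 regions were higher and 6462 lower on LS chow. On LS chow 632 regions were higher and 195 lower in CRL rats, and on HS chow 179 were higher and 1812 lower, while the authors' q-value column under 0.05 passed 21 and 105. Acbd4 had its promoter at 31.4% in MCW and 5.98% in CRL kidney on LS chow, and at 60.2% and 19.9% on HS chow. On HS chow the Ndufa10 promoter was at 62.2% and 26.8%, Runx1 at 31.5% and 8.35%, and the Nnat and Blcap promoter at 52.0% and 28.8%. On LS chow Gnas was at 13.6% in MCW and 44.3% in CRL kidney, Pax2 at 21.0% and 50.8%, and Lcp2 at 49.1% and 72.6%. T cell identity genes carried a lower region in CRL kidney at 3 of 16 genes on LS chow (0.151 expected, adjusted permutation p = 0.0204), and imprinted genes at 11 of 31 on HS chow (4.07 expected, adjusted permutation p = 0.0374). Neither passed against genes that could have passed. Between LS and HS chow in kidney, 67 increases and 67 decreases were shared (5.00 and 11.2 expected), and 42 regions were higher in CRL rats on LS chow and lower on HS chow.

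Age was compared in MCW rats on LS chow, at 10 against 7 weeks. Blood differed at 218 regions, of which 123 were higher and 95 lower at 10 weeks. Neurl1b, a ubiquitin ligase of the Notch pathway, rose from 32.1% to 60.5%, with an adjusted p of 7.17e-12 in the authors' deposited table, and Trappc6a from 25.7% to 53.1%. Sod3 fell from 87.9% to 66.8% and the 2 identical copies of a Cyp4f5 region from 83.1% to 62.6%. The antisense transcript Hoxaas3 of the HoxA cluster had 10 of 20 regions called, each higher. In kidney 100 regions were higher and 1645 lower at 10 weeks, and with no minimum difference 7539 and 10608. The means of the 7 week kidney group were equal (within 0.01 percentage points) in 10.0% of the regions that its 2 tables share. The authors' q-value column under 0.05 passed 12 regions in blood and 42 in kidney. Bhmt, which remethylates homocysteine in liver and kidney, fell at its promoter from 58.6% to 26.1%, Ggt1 from 48.4% to 17.2% and Hnf4a, a transcription factor of the proximal tubule, from 46.0% to 21.6%. Imprinted genes carried a lower region at 13 of 28 genes (2.51 expected, adjusted permutation p = 0.0034; 0.0272 against genes that could have passed), with 8 of 19 Gnas regions lower. Kidney epithelial markers were lower at 9 of 32 genes (2.14 expected, adjusted permutation p = 0.0051) and T cell identity genes at 5 of 16 (1.10 expected, adjusted permutation p = 0.0363). Neither of these passed against genes that could have passed. The MCW LS group at 10 weeks stands in the MCW salt tables, the colony tables on LS chow, the age tables and its own kidney against blood table. The directions of their counts, and the changes of Sod3 and of the imprinted genes in them, are therefore not independent. Kidney of that group was the less methylated side at most called regions of its salt, colony and age comparisons.

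Called regions lay in promoters less often than tested regions did. Against all tested regions, promoters were fewer among the calls of each comparison, with odds ratios between 0.135 (MCW LS at 7 weeks, kidney against blood) and 0.735 (blood on HS chow, CRL against MCW). Most promoter regions were under 10% in both groups: in MCW blood, HS against LS chow, 1845 of 10576 reached it in either group.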

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

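The tests with the authors' q-value column, with the difference of the group means, with identical regions counted once, and with a background of regions at 10% or more in either group were chosen after seeing the data. Directions of the counts kept except where said, and where a value moved the cause was not tested, beyond a looser or stricter limit passing more or fewer regions. Counts of calls stayed within 1.5 times for autosomes only, for an adjusted p under 0.1, for merged regions, for the difference of the group means and for identical regions counted once. Leaving out regions with fewer than 3 CpGs moved nothing, since the tables hold none under 5.

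Counts follow in the order of salt in MCW blood, MCW kidney, CRL blood and CRL kidney, colony in blood on LS, kidney on LS, blood on HS and kidney on HS chow, age in blood and kidney, and kidney against blood in MCW LS at 10 weeks, MCW HS, CRL LS, CRL HS and MCW LS at 7 weeks. With no minimum difference they were 2977, 9184, 3205, 13399, 3813, 12469, 2352, 7505, 3120, 18147, 24930, 30125, 30346, 26777 and 38540. With at least 20 percentage points they were 12, 1385, 10, 223, 45, 170, 57, 242, 16, 285, 7923, 7583, 7039, 7394 and 7470, and with at least 25 they were 1, 553, 1, 83, 17, 59, 10, 55, 5, 95, 6309, 5648, 5662, 5826 and 5835. The authors' q-value column under 0.05 gave 7, 372, 7, 57, 74, 21, 64, 105, 12, 42, 2793, 2391, 2569, 2586 and 2436. At least 5 percentage points moved the salt counts to 443 (MCW blood), 395 (CRL blood) and 2627 (CRL kidney), the colony counts to 888, 1582, 821 and 3053 and the age counts to 670 and 3006. An adjusted p under 0.01 moved salt to 87 (MCW blood), 83 (CRL blood) and 955 (CRL kidney), colony in kidney on LS chow to 457 and age in blood to 142, and an unadjusted p under 0.05 moved salt in blood to 252 (MCW) and 236 (CRL) and age in blood to 352. With no minimum difference the share higher turned to 44.6% for salt in CRL kidney and 48.2% for colony in kidney on LS chow, and with at least 20 percentage points age in blood had 8 regions higher and 8 lower.

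Of the gene list tests in either direction, 30 of 255 passed, against 5 with gene body regions only and 4 with regions that could have passed. Of those for increases 12 of 255 passed, against 9 with regions that could have passed, and of those for decreases 18, against 5. Comparisons with a promoter odds ratio above 1 numbered 0 against all tested regions and 15 against those that could have passed, a background that an unmethylated region enters only by its change, so that the 15 decide nothing. The shared increases of the 2 colonies in blood passed with a ratio of 16.7 within 1 kb (3 shared) and 12.0 by gene (2 shared). By the same rules 7 regions and 4 genes higher in MCW blood were lower in CRL blood, more than were shared. The shared increases of blood and kidney in CRL rats passed by gene with a ratio of 3.07, while the shared decreases no longer passed at 4.75 with regions that could have passed and at 5.18 by gene. By gene, 2309 genes were called in the same direction in all 5 tissue tables. Of the named regions, 506 were still called at 20 percentage points and 282 were not, and by the q-value 264 and 524.

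No paired analysis was possible because the tables hold no value per pool, although each pool gave both tissues. For the same reason a coverage minimum, a quasi-binomial model, limma, Fisher's exact test on counts, leaving out each pool and a block for the replicate were not run. The nearest gene and promoters within 1 kb were not run for lack of an rn5 annotation. What depth limits is unknown, since the tables give none.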

Other observations

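Other gene groups of T cells and immune signalling held called regions between kidney and blood, of which activation and exhaustion genes in MCW HS passed in either direction against both backgrounds. In MCW LS at 10 weeks, activation and exhaustion genes carried a called region at 15 of 16 tested genes (3 higher and 13 lower), and in MCW HS at 16 of 18 (9.15 expected, adjusted permutation p = 0.0068, 0.0102 against genes that could have passed). Helper lineage transcription factors were called at 13 of 19 genes in MCW LS at 10 weeks (2 higher, 12 lower), cytokines and cytotoxic effectors at 4 of 8 (1 and 3), trafficking and tissue residency at 5 of 13 (2 and 4), innate and inflammasome signalling at 4 of 14 (0 and 4) and aryl hydrocarbon and xenobiotic response at 2 of 7 (0 and 2). One-carbon metabolism was called at 10 of 29 genes (0 and 10), DNA methylation machinery at 4 of 11 (2 and 3), B cell markers at 5 of 10 (3 and 3), natural killer cell markers at 1 of 4 (0 and 1) and homeobox developmental regulators at 29 of 64 (8 and 22). Homeobox genes were lower less often than matched genes in MCW LS at 7 weeks, at 17 of 65 (26.7 expected, adjusted permutation p = 0.0468, and 0.034 against genes that could have passed).

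All tests weighed below were chosen after the result was seen, except that of unstable group means. In the kidney preparations, more T cell identity genes than expected carried regions more methylated than in blood in all 5 conditions. If other leukocytes were the whole cause, genes that all leukocytes express would carry no excess of higher regions. Against matched genes that could have passed, the lowest adjusted permutation p for their excess over the 5 tables was 0.007. In CRL LS the permutation p was 0.282 before adjustment. Whether other leukocytes are as unmethylated at these genes as T cells was not tested, so that the excess cannot decide this. That background takes in a region unmethylated in blood only by its change. Against all matched genes the permutation p was also low, at 0.0002 before adjustment in MCW HS. Cells other than leukocytes in the kidney preparations fit: in 4 of 5 tables more genes of the pan-leukocyte list, written before its test, carried a higher region than matched genes did, though more of them carried a lower one (5 higher and 7 lower of 14 in MCW LS at 10 weeks), with Nckap1l at 36.3%, Arhgap25 at 25.3%, Dok2 at 62.4% and Ikzf1 at 36.9% in kidney in MCW LS at 10 weeks, and 4 of its 30 genes also stand in fixed lists. No sort or gate is given, and expression was not measured. A difference between kidney and blood T cells stays open, untested, and so do other leukocytes.

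In MCW kidney preparations most called regions were more methylated on HS than on LS chow. Fewer cells other than T cells on HS chow would lower regions that the CRL tables call higher in kidney, yet 81.2% of these rose (lower quartile of the change 2.49 percentage points), which argues against it as the whole cause. As part of the cause, fewer such cells stay open. Of 4700 regions that the CRL tables call lower in kidney, 99.0% rose, by a median of 11.3 percentage points. Regions without a tissue difference rose at 70.7%, by a median of 2.01. Kidney epithelial markers carried a higher region at 14 of 30 genes and a lower one at 0, though the list did not pass the threshold against matched genes. Incomplete conversion would raise unmethylated regions, which moved by a median of 0.353 percentage points, and loss of methylated molecules alike at every region would raise regions at 60 to 90% without a tissue difference, which moved by 2.01, so that both are argued against. A loss uneven among regions stays open, since imprinted genes with regions at 30 to 60% in blood had kidney medians of 22.5% in MCW LS and 40.4% in MCW HS in the kidney against blood tables. Kidney of MCW LS at 10 weeks was also lower at most called regions against MCW LS at 7 weeks (1645 lower, 100 higher). Against it, CRL LS kidney was higher at 632 regions and lower at 195. Neither comparison had HS chow, so that a low level of that group alone, whatever its cause, stays open beside the chow. In CRL kidney the share that rose was 56.3% (95% interval 49.2% to 63.2%, binomial over regions of the same pools as if they were independent), and there fewer cells other than T cells and an effect of chow cannot be told apart, since the interval includes 50%, while the chow, and the lane or library batch, which is not given per sample, stay open in both colonies.

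Kidney preparations were less methylated than blood at most called regions. The means of the same group differed between deposited tables to an extent that varied by group, but among called regions with both means equal in another table (within 0.01 percentage points) the share lower in kidney was 84.9% at the lowest, which argues against unstable means there. These regions were a small part of the calls, from 1630 of 12995 in MCW LS at 10 weeks to 45 of 13526 at 7 weeks, where kidney means were equal in 10.0% of shared regions. Loss of methylated molecules from the kidney libraries would lower imprinted genes, whose median difference in MCW HS was 2.29 percentage points, which argues against it in that condition alone, since in MCW LS at 10 weeks the kidney median was 22.5% against 41.6% in blood. Markers of other cells often carried a region lower in kidney, here in MCW LS at 10 weeks. These were 24 of 33 kidney epithelial markers (2 carried a higher one), 11 of 20 endothelial and stromal markers (1 higher) and 9 of 12 myeloid markers (0 higher). They go with other cells in the kidney preparations, though the epithelial markers did not pass the threshold against matched genes that could have passed. How much of the difference lies in other cells and how much in T cells of the tissue stays open.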
